A study of Danio rerio with 6 samples.

How the data were processed

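RNA-seq was made from pools of zebrafish embryos (F1) of the AB strain whose parents (F0) had been kept in normal water or in water with copper, at 0.078 µM or 0.156 µM, per the labels. The parents were exposed for more than 21 days from 3 months of age, and the embryos themselves grew in normal water. Pools of 50 to 60 embryos were lysed at 24 or 96 hours post fertilization (hpf), and they were picked by phenotype, per the design text of the series. The 3 parental groups and 2 stages give 6 groups with 1 library each. The design text speaks of 3 biological repetitions per group. Whether these were pooled into the library of each group is not given in the sources used here.

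The deposited values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library), 1 value per annotated transcript and library, per the file headers. Trimmomatic, TopHat2 and Cufflinks 2.1.1 are named in the submitters' processing notes, with no settings. Genome build, annotation release and the scaling between libraries are not given in the sources used here. FPKM is already divided by library size and transcript length, so the numbers of fragments are not known and no count test was run. FPKM of single transcripts also depends on how fragments shared by several transcripts of a gene were divided among them, so a value listed at 0 is not taken as absence.

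Each library lists the same 58002 identifiers, of which 57761 are Ensembl transcript IDs and 241 are Ensembl gene IDs. The files do not pair transcript IDs with genes, and the gene tables used here hold gene IDs only. Of the 241 gene IDs, 8 had a symbol, and none of these exceeded 0.282 FPKM. The 42 lists of pathway and cell type genes fixed before the data were examined had 0 members among these, so no list was tested, and the results are given per transcript instead of per gene as had been planned. Chromosome positions and exon annotations were not used here.

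Total depth is unknown, and sums of FPKM (476499 to 562987) do not measure it. Relative depth was read from the steps of low values: the log2 ratios of values between 0.005 and 0.3 FPKM pile up at the ratio of what 1 fragment is worth in each library. The pile was sought only at log2 ratios of at most 0.3 in size, so a larger difference in depth could not have been found. Between the control and the 0.078 µM library at 24 hpf, 428 of 6159 such transcripts lay in a single bin of 0.01, against a median of 5 per bin. At 96 hpf the fullest bins held 183 of 4955 transcripts for 0.078 µM and 234 of 4772 for 0.156 µM, against a median of 4. From these steps the 0.078 µM and 0.156 µM libraries were 1.01 and 1.04 times as deep as control at 24 hpf, and 1.07 and 1.07 times at 96 hpf. The 96 hpf control library was 0.954 times as deep as the 24 hpf control library. This ratio rests on a smaller pile, with 75 of 3963 transcripts in the fullest bin against a median of 5. Intervals for counting error need the number of fragments and are not given.

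Values were compared as differences of log2(FPKM + 1), that is with a pseudocount of 1, which understates the change of low transcripts. Transcripts with at least 1 FPKM in at least 1 of the libraries compared were kept: the 3 libraries of a stage for copper, and all 6 for comparisons between stages. A transcript was counted as different at a fold of 2 on this scale. Each parental group has 1 library per stage, so no test was run within a stage and the counts describe these libraries. In place of replicates, each copper comparison was set beside the difference between the 0.156 µM and 0.078 µM libraries, which does not use control. Transcripts at least 2-fold apart from both other groups of their stage, in the same direction, were also counted for each of the 3 parental groups in turn. A test over both stages, added after seeing the data, fitted log2(FPKM + 1) of all 6 libraries with limma 3.58.1 in R 4.3.3, with the stage as a block and copper at either dose against control as the term, a variance trend, and Benjamini-Hochberg adjustment at 0.05. Its residual error is the variation between doses and between stages in the size of the change, and its p-values measure that spread and not one between separate clutches. The same fit was repeated with the parental groups as terms, and with each of the 9 choices of 1 parental group per stage in the place of control.

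Comparisons of both doses with the same control library share its error. Unchanged groups with a shared control were simulated in 100 draws, with errors resampled in 20 bins of level from the difference of the 2 copper libraries divided by the square root of 2. That error includes any true difference between the doses. It also gives every simulated library the large differences of both copper libraries, so the simulated shared numbers may be too high. Position along development was measured as the slope, across transcripts, of a copper change on the 96 minus 24 hpf change of the remaining group, which shares no library with it.

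The procedure was tested on simulated data. With 200 transcripts changed by 1.5 on the log2 scale in both copper libraries, 97.5% of them were recovered at both doses at 24 hpf (24537 transcripts) and 99.5% at 96 hpf (27496 transcripts). In the same draws 557 and 481 unchanged transcripts were also called at both doses. For the fit over both stages (30156 transcripts), 98% of 200 transcripts changed by 1.5 were called, with 11 unchanged ones. In both simulations the 200 were drawn only from transcripts with a mean log2(FPKM + 1) of at least log2(11), so recovery at lower levels is not known. The errors simulated for the fit were normal, so large jumps of single libraries were not imitated.

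The rule for named items asked for gene symbols and was kept without that part. Among transcripts above 0 in all 3 libraries of a stage and at 5 FPKM or more in at least 1, the one with the highest and the one with the lowest weaker change of the 2 doses is named per stage, the next one where an ID was already named. This gives 2 IDs that were higher and 2 that were lower. The parts of the rule that rank single doses and list members were not applied. Alternatives were pseudocounts of 0.1 and 5, no filter, filters of 5 FPKM in 1 library and of 0.1 FPKM in all, median ratio rescaling, rescaling to 1000000 per library (TPM), quantile normalization, leaving out transcripts listed at 0, and folds of 1.5 and 4. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.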

Results

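RNA-seq of whole zebrafish embryos addressed whether exposure of the parents to copper, an essential metal that is toxic in excess, goes with altered gene expression in offspring raised without added copper. The data are 6 libraries, 1 for each of 3 parental groups (control, 0.078 µM and 0.156 µM copper) at 24 and 96 hpf. Between 21999 and 22301 transcripts reached 1 FPKM in the libraries of 24 hpf, and between 25008 and 25271 in those of 96 hpf. The 10 most abundant transcripts held 6.04% to 6.22% of all FPKM at 24 hpf and 9.17% to 9.84% at 96 hpf. Between 11.9% and 14.2% of the identifiers of a library were listed at 0. A further 9835 to 10002 identifiers per library were above 0 but below 0.001 FPKM, so a value above 0 does not mark detection. The total depth is unknown, and from the steps of low values the libraries of a stage lay within 1.07 times of the control library's depth. These steps were sought only at ratios near 1. There are no replicates within a stage, so the differences at a single stage carry no replicate error and were not tested. Embryos were selected by phenotype before lysis, so parental exposure and that selection are not separated. The title of the series names DNA methylation, but genes of the methylation machinery could not be looked up, as the files do not pair transcripts with genes.

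At 24 hpf, among transcripts above 0 in all 3 libraries and at 5 FPKM or more in at least 1, the largest increase common to both doses on the log2(FPKM + 1) scale was that of ENSDART00000005191, which had 0.00869 FPKM in control offspring, 86.1 FPKM in offspring of parents kept at 0.078 µM and 62.4 FPKM in those at 0.156 µM. The largest common decrease among them was that of ENSDART00000161538, with 400.3 FPKM in control and 6.33 and 9.97 FPKM in the copper groups. With a pseudocount of 0.1 in place of 1 its decrease ranked 10 among 11866 transcripts, while the ranks of the other named transcripts did not change with a pseudocount of 0.1 or 5. At 96 hpf its values were 20.9, 29.5 and 16.2 FPKM, with log2 changes of 0.48 and -0.35. With parents at 0.078 µM, 554 of 24537 transcripts were at least 2-fold higher and 586 at least 2-fold lower than control, 4.65% in all. With parents at 0.156 µM, 741 were higher and 594 lower, 5.44% in all. Between the copper libraries, 729 transcripts were higher and 569 lower at 0.156 µM than at 0.078 µM, 5.29% in all. The number that differed between the doses thus lay between the numbers that differed from control. The median log2 change over control was 0.01 at either dose. Percentiles 5 and 95 were -0.58 and 0.60 at 0.078 µM, -0.61 and 0.70 at 0.156 µM, and -0.60 and 0.68 between the doses. These counts move by more than 1.5 times with the pseudocount, the filter and the fold, as given with the alternatives.

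Among transcripts chosen by the same limits in the libraries of 96 hpf, ENSDART00000005191 again had the largest common increase, with 0.00874 FPKM in control, 87.0 FPKM at 0.078 µM and 103 FPKM at 0.156 µM. The next largest was that of ENSDART00000132135, with 0.0364 FPKM in control and 38.0 and 37.6 FPKM in the copper groups, whereas the libraries of 24 hpf held 39.1 to 43.9 FPKM of it. ENSDART00000104338 had the largest common decrease among these transcripts, with 35.2 FPKM in control and 0.00775 and 0.00742 FPKM in the copper groups, and it stood at 0.00621 to 0.00661 FPKM in the libraries of 24 hpf. The files do not pair these 4 transcripts with genes. With parents at 0.078 µM, 511 of 27496 transcripts were at least 2-fold higher than control and 597 lower, 4.03% in all. At 0.156 µM, 618 were higher and 663 lower, 4.66% in all. Between the doses 1156 transcripts differed, 619 higher and 537 lower at 0.156 µM, again a number between those that differed from control.

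**Figure D1:**
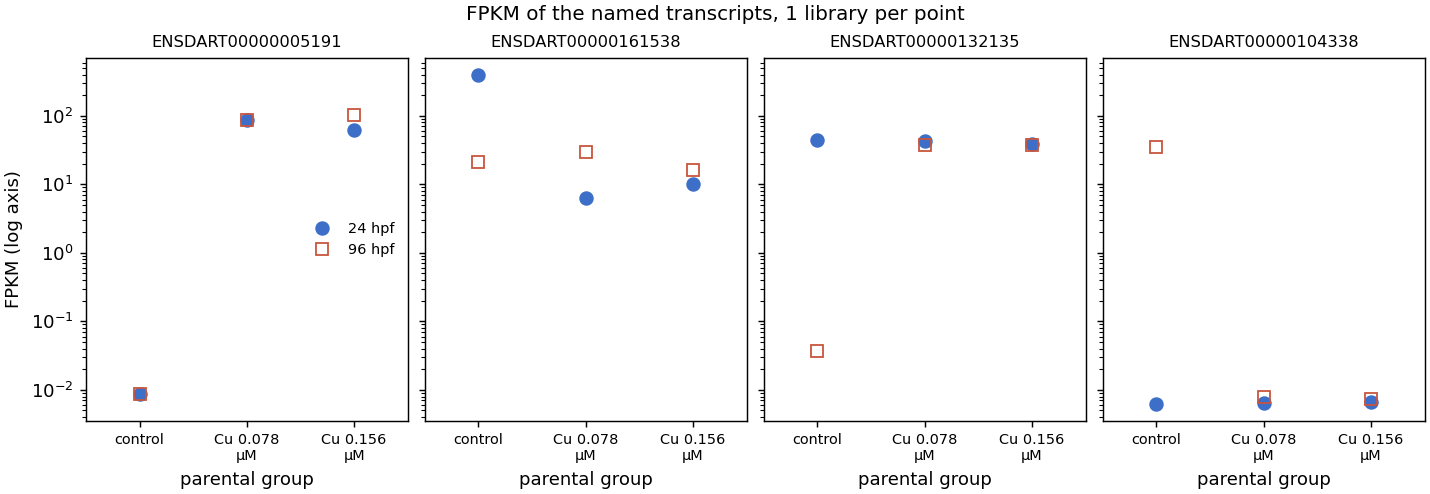
FPKM (vertical, log axis) of the 4 named transcripts in each parental group (horizontal) at 24 hpf (filled circles) and 96 hpf (open squares), 1 library per point. ENSDART00000005191 is near 0.0087 in both control libraries and between 62.4 and 103 in the 4 copper libraries, whereas the other 3 are 2-fold apart from control at 1 of the stages.

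**Figure D2:**
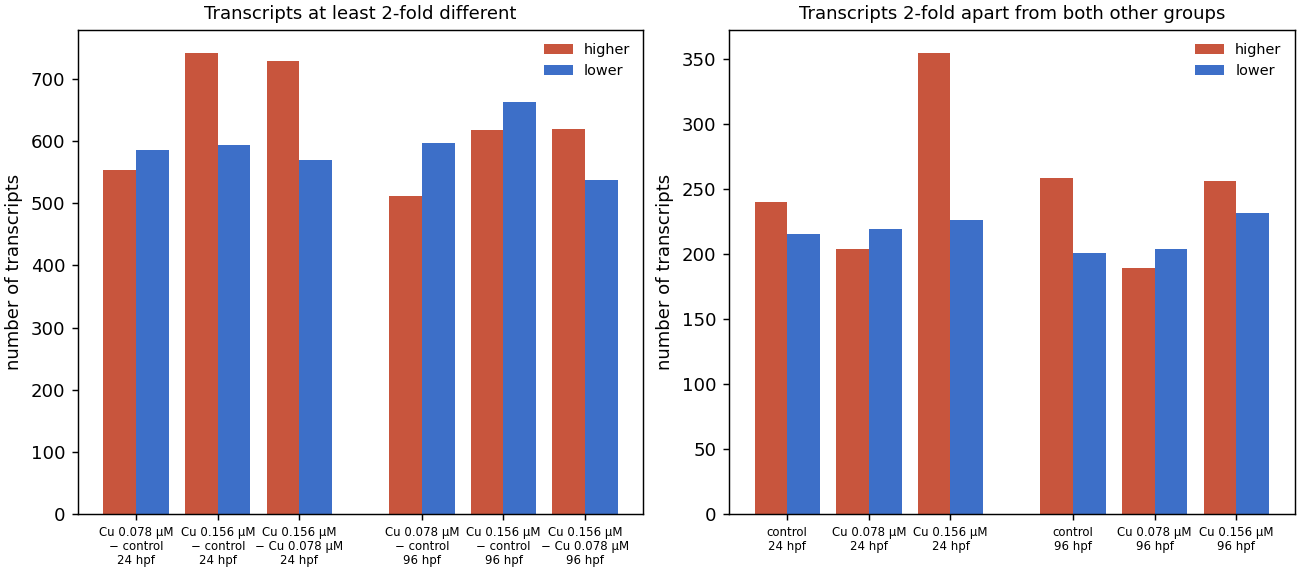
Left, number of transcripts at least 2-fold higher (red) or lower (blue) in each comparison within a stage, with 1 library per group. Right, number at least 2-fold higher or lower than both other parental groups of the stage, where the tallest bar is that of 0.156 µM at 24 hpf (354 higher) and control has 240 and 258 higher at 24 and 96 hpf.

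Both doses were compared with the same control library. At least 2-fold higher than control at both doses were 215 transcripts at 24 hpf, and 240 were lower at both. At 96 hpf, 201 were higher and 258 lower at both. Independent lists of the same sizes would share 16.7 higher and 14.2 lower transcripts at 24 hpf, and 11.5 and 14.4 at 96 hpf. Unchanged groups simulated against a shared control shared 269 higher and 268 lower transcripts on average at 24 hpf, and 234 and 235 at 96 hpf. At 24 hpf the 215 higher transcripts lay below all 100 draws, which ranged from 236 to 308, and the 240 lower ones lay within the range of 214 to 312. At 96 hpf both observed numbers lay within the draws, which ranged from 197 to 285 for higher and from 203 to 275 for lower transcripts. Every simulated library drew on the large differences of both copper libraries, which may make the simulated numbers too high. The 215 are therefore not read as a deficit. Across transcripts, which are not independent replicates, the changes at both doses had Pearson's r = 0.478 and Spearman's rho = 0.463 at 24 hpf, and 0.519 and 0.496 at 96 hpf. Simulated unchanged groups gave a Pearson's r of 0.499 and 0.50. Errors of equal size in all simulated libraries give an r near 0.50 whatever the data, so this value was fixed in advance. The covariance was 0.129 at 24 hpf against 0.141 in the simulation, whose draws ranged from 0.124 to 0.155. At 96 hpf it was 0.121 against 0.113, with draws from 0.102 to 0.125. Both observed covariances lay within the range of the draws. Observed and simulated covariances follow from the spreads of the differences from control and between the doses. They restate that these spreads are alike and are no separate evidence. A single control library cannot be split, so part or all of the overlap beyond that of independent lists may come from sharing it.

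**Figure D3:**
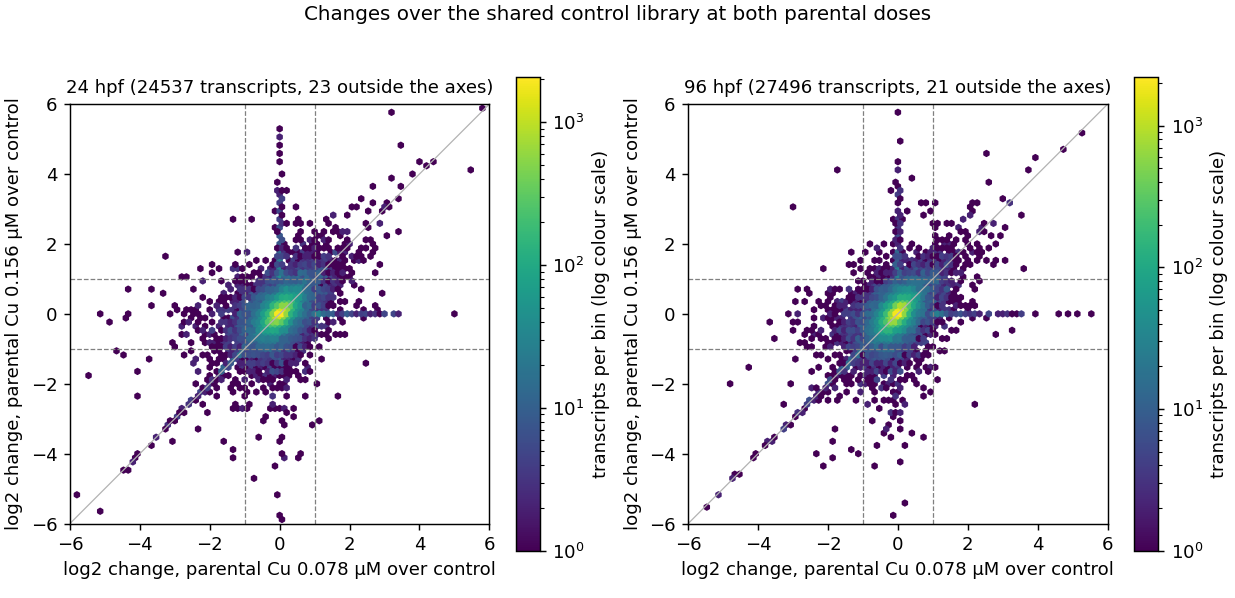
Log2 change over control with parents at 0.078 µM (horizontal) and 0.156 µM (vertical) at 24 hpf (left) and 96 hpf (right), with colour for the number of transcripts per bin on a log scale, dashed lines at a fold of 2, and 23 and 21 transcripts outside the axes. The cloud leans along the diagonal, with r = 0.478 and 0.519. A shared control with errors of equal size gives about 0.50 by construction, and the simulation gave 0.499 and 0.50.

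Each parental group was set against the other 2 in the same way. Control was at least 2-fold apart from both copper groups in 455 transcripts at 24 hpf, against 423 for 0.078 µM and 580 for 0.156 µM. At 96 hpf the numbers were 459 for control, 393 for 0.078 µM and 487 for 0.156 µM. With at least 0.1 FPKM required in all 3 libraries, a filter chosen after seeing the data, they were 144, 120 and 179 at 24 hpf and 120, 111 and 147 at 96 hpf. Control was thus in the middle at either stage and with either filter. Some transcripts went from near 0 to a high level. Below 0.1 FPKM in control and at 5 FPKM or more in both copper groups were 19 transcripts at 24 hpf, against 19 for 0.078 µM and 27 for 0.156 µM in its place. At 96 hpf these were 8, 12 and 29. At 5 FPKM or more in control and below 0.1 in both copper groups were 22 transcripts at 24 hpf, against 21 and 35. At 96 hpf these were 40, 24 and 25, so that control had the highest of the 3 numbers in this case.

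A fit over both stages was added after seeing the data. It takes the stage as a block and leaves 3 residual degrees of freedom, on the assumption that copper acts alike at both stages and doses. The libraries of both stages stand in for replicates of a parental group. Its p-values thus measure the spread between doses and stages, and not one between separate clutches or parents. Of 30156 transcripts, 1 passed an adjusted p of 0.05 (limma, Benjamini-Hochberg adjustment), ENSDART00000005191, which was higher by 6.39 on the log2 scale over the 4 copper libraries, with an adjusted p of 0.00590. The other 3 named transcripts had an adjusted p of 0.951 each in this limma fit. Unadjusted p-values below 0.05 were found for 1462 transcripts, 4.85% of those tested. With another parental group in the place of control at either stage or both, the same fit called 0 to 3 transcripts, and 6 of the 9 choices, that of control included, called at least 1. With the parental groups as terms, which leaves 2 residual degrees of freedom, ENSDART00000005191 was not called for 0.156 µM against control, with or without the variance trend. For 0.078 µM against control it was not called without the trend.

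The copper changes at 24 hpf were then compared with those at 96 hpf, which share no library, so that unrelated changes would give 0. Over 30156 transcripts Pearson's r was 0.0696 and Spearman's rho 0.0229 for 0.078 µM against control. For 0.156 µM against control r was -0.0131 and rho -0.0331, and between the doses r was 0.0186 and rho 0.00524. Over the alternatives, r for 0.078 µM ranged from 0.0268 with transcripts listed at 0 left out to 0.125 with a pseudocount of 5. For 0.156 µM it ranged from -0.0358 with a pseudocount of 5 to -0.00193 with a pseudocount of 0.1.

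The largest differences in the data were those between 24 and 96 hpf, the period in which the embryo completes its main organs and hatches. In control offspring, 6169 of 30156 transcripts were at least 2-fold higher at 96 hpf and 3510 lower, 32.1% in all. With parents at 0.078 µM the numbers were 5885 and 3360, and at 0.156 µM they were 6315 and 3704. Quantile normalization changes these splits, to 4864 higher and 4371 lower in control, 4802 and 4231 at 0.078 µM, and 5073 and 4580 at 0.156 µM. Rescaling to 1000000 per library raised the share of higher transcripts instead, and also the totals. It gave 8734 and 3272 in control, 8109 and 3402 at 0.078 µM, and 8389 and 3816 at 0.156 µM. Such rescaling lowers the pseudocount relative to the values, which can raise totals. Sums of FPKM were lower at 96 hpf than at 24 hpf in each parental group, 476499 against 562987 in control. The rescaling thus raises the values of 96 hpf more, which moves the share toward higher transcripts by construction. In control the median log2 change between the stages went from 0.07 to 0.28. In all 3 parental groups 4387 transcripts were higher, 71.1% of those of control, and 1902 were lower, 54.2% of those of control. From below 0.1 FPKM at 24 hpf to at least 10 FPKM at 96 hpf went 163 transcripts in control, 146 at 0.078 µM and 165 at 0.156 µM, of which 72 did so in all 3, 44.2% of those of control. From at least 10 FPKM at 24 hpf to below 0.1 FPKM at 96 hpf went 69, 50 and 83 transcripts, of which 17 did so in all 3, 24.6% of those of control. Across transcripts, Pearson's r of the change between the stages was 0.867 between control and 0.078 µM, 0.836 between control and 0.156 µM, and 0.850 between the copper groups, none of which share a library. Changes of at least 2-fold in opposite directions were found in 115, 132 and 119 transcripts.

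Whether the copper libraries lay earlier or later in development than control was examined with the transcripts that differ between the stages, taken from the parental group left out of the comparison. For 0.078 µM, the 1881 transcripts at least 4-fold higher at 96 hpf had a median log2 change over control of 0.00 at 24 hpf, with quartiles of -0.11 and 0.12, and of -0.01 at 96 hpf. For 0.156 µM, the 1704 such transcripts had medians of 0.00 and -0.02. The transcripts at least 4-fold lower at 96 hpf, 688 and 566 in number, had medians of 0.02 at either dose at 24 hpf, and of 0.00 and 0.01 at 96 hpf. Each class is at its lower level at 1 of the stages, 24 hpf for the higher class and 96 hpf for the lower class. The pseudocount understates changes of low transcripts, so the medians at that stage can show little of a shift. Over all transcripts the slope of the copper change on the change between the stages was -0.00802 at 0.078 µM and -0.0173 at 0.156 µM at 24 hpf, and -0.0120 and -0.0149 at 96 hpf. Between the doses it was -0.00632 and 0.000223. For scale, the change between the stages of control itself had a slope of 0.817 on that of 0.156 µM and of 0.885 on that of 0.078 µM, and the change of 0.078 µM had a slope of 0.849 on that of control.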

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

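The tests that weigh explanations in this part were chosen after the results they measure were seen. Some transcripts differed from control at both doses in 1 direction at 24 hpf and in the opposite direction at 96 hpf. Control was at least 2-fold higher than both copper groups at 24 hpf and lower than both at 96 hpf for 8 transcripts, and the other way round for 9. The difference between the stages was not tested. The sum of 17 compares with 24 for 0.078 µM and 23 for 0.156 µM, each set against the other 2 groups in the same way.

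The transcripts 2-fold apart from control at both doses were weighed against the spread between any 3 libraries, 1 of which is shared. Control was set apart by 0.784 times as many transcripts at 24 hpf and 0.943 times as many at 96 hpf as the copper group with the larger number, and by 1.08 and 1.17 times as many as the one with the smaller number. Such ratios may come from that spread alone, but an effect of 1 dose would also lower the first of them, so they do not decide between the explanations. An effect of parental copper common to both doses stays open. The covariance of the changes minus the simulated one was -0.0125 at 24 hpf and 0.00736 at 96 hpf. Both lay within the range of the draws. Fewer transcripts were higher at both doses at 24 hpf than in any draw, but the simulated numbers may be too high, so this decides nothing. The simulated spread itself also holds any difference between the doses. With 1 library per group and stage an effect common to both doses cannot be told apart from differences between parents or in the selection of embryos.

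Large differences often involved values near 0: of transcripts at 5 FPKM or more in at least 1 library that set control apart at 24 hpf, 49.7% had a value below 0.1 FPKM, and so had 49.4% of those that set a copper group apart; at 96 hpf the shares were 53.2% and 52.1%. Selecting 2-fold differences raises such shares by itself, so their size decides nothing. The value of 1 fragment differed by at most 0.101 on the log2 scale between control and the copper libraries of a stage. It was sought only at ratios near 1, so a large difference in depth could not have been found and is not excluded. Fragments that the abundance estimation assigned to another transcript of the same gene may give such values, as may a true switch between transcripts or a sequence variant of the parents. These cannot be told apart here. A test for another transcript of the gene that moves the opposite way needs the gene of each transcript. Even then it would not separate misassigned fragments from a true switch.

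Control was set apart from both copper groups, in the same direction at both stages, by 33 transcripts, against 24 for 0.078 µM and 36 for 0.156 µM. The mean per group and direction was 15.5, where independent lists would share 1.83. Transcripts set apart in 1 group at 24 hpf and in another at 96 hpf averaged 12.8 per pair and direction, a ratio of 0.828, so transcripts whose estimate varies between libraries whatever the group may account for most of the excess. A lasting effect of parental copper stays open: control had 0.917 times the number of the larger copper group, which neither requires nor excludes that some of the 33 follow copper.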

How the results depend on the processing

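The settings tried here were planned, except the filter of 0.1 FPKM in all libraries and the limma fit, which were chosen after seeing the data. Of 245 alternative values, 37 could not move, because a filter leaves the values of a named transcript as they are and dropping the filter leaves the counts as they are. Of the other 208, 131 lay close to the reported ones and 77 moved. Close meant within 0.05 for a correlation, 0.02 for a slope, 1 for the log2 change of a named transcript, and 1.5 times for a count. The limit for slopes exceeds every slope of a copper change, and that for correlations exceeds the one of 0.156 µM between the stages. Being close is therefore no sign of stability for these values. Median ratio rescaling, quantile normalization and leaving out transcripts listed at 0 moved none of the totals by over 1.5 times. Applying no filter is void for all counts at a fold of 2, since a fold of 2 with a pseudocount of 1 needs at least 1 FPKM. In the order 0.078 µM against control, 0.156 µM against control and 0.156 µM against 0.078 µM, the 24 hpf counts (1140, 1335 and 1298) became 2238, 2578 and 2411 with a pseudocount of 0.1, and 171, 223 and 201 with a pseudocount of 5. They were 327, 414 and 380 with at least 5 FPKM in 1 library, 412, 527 and 473 with at least 0.1 FPKM in all, 2504, 2891 and 2713 at a fold of 1.5, and 236, 271 and 274 at a fold of 4. The 96 hpf counts (1108, 1281 and 1156) became, under the same settings in that order, 2202, 2495 and 2315, then 155, 203 and 179, then 288, 368 and 316, then 376, 478 and 428, then 2449, 2972 and 2645, and last 219, 258 and 229. The mean of the copper comparisons was 0.925 to 0.999 times the count between the doses at 24 hpf over these settings and the rescalings, and 0.998 to 1.04 times at 96 hpf. Transcripts different at both doses became 1069, 71, 147, 144, 1122 and 92 at 24 hpf (455) and 1061, 76, 139, 120, 1139 and 103 at 96 hpf (459) under the same 6 settings, and 714 at 96 hpf after rescaling to 1000000 per library. Which side of a split was larger changed in 14 of 121 splits under alternatives, 8 of them for both doses and 0 for the stages. At both doses at 24 hpf, 215 higher and 240 lower became 622 and 447 with a pseudocount of 0.1, 78 and 69 with at least 5 FPKM, 361 and 305 after rescaling to 1000000, 591 and 531 at a fold of 1.5, and 81 and 63 with at least 0.1 FPKM in all. At 96 hpf, 201 and 258 became 573 and 488 with a pseudocount of 0.1, 196 and 188 without transcripts listed at 0, and 78 and 42 with at least 0.1 FPKM in all, but 18 and 58 with a pseudocount of 5. The larger side at both doses is therefore not a stable result. Differences between 96 and 24 hpf, in the order control, 0.078 µM and 0.156 µM (9679, 9245 and 10019), became 3351, 3131 and 3397 with a pseudocount of 5, 5867, 5694 and 5957 with at least 5 FPKM in 1 library, 16423, 16153 and 16812 at a fold of 1.5, and 2421, 2270 and 2569 at a fold of 4. Other pseudocounts, other folds and stricter filters change counts by construction. Rescaling to 1000000 per library does so in part, through the pseudocount and the sums of FPKM. For the remaining settings the cause was not tested. Rescaling moved the median log2 difference between the stages by up to 0.21, and those of the copper comparisons by up to 0.04. The correlation between the stages for 0.078 µM (0.0696) was 0.125 with a pseudocount of 5 and 0.114 with at least 5 FPKM, but 0.0268 without transcripts listed at 0, 0.0373 with a pseudocount of 0.1 and 0.0394 with at least 0.1 FPKM in all. The slopes of both doses against control stayed negative at either stage, but their size changed. At 96 hpf the slope for 0.156 µM (-0.0149) was -0.00657 with a pseudocount of 0.1 and -0.0230 with 5. That for 0.078 µM (-0.0120) was -0.00691 with at least 0.1 FPKM in all. The log2 change of ENSDART00000005191 for 0.078 µM at 24 hpf (6.43) was 9.63 with a pseudocount of 0.1 and 4.18 with 5. The gene list alternatives, and those of named genes with a symbol, were not run, as no transcript was paired with a gene. With the stage as a block, limma called 1 transcript for copper against control with a variance trend and 1 without. With the parental groups as terms and 2 residual degrees of freedom, limma called 3 transcripts for 0.078 µM against control with the trend and 0 without, and the cause was not tested. For 0.156 µM against control and between the doses it called 0 either way, with 1400 and 1228 unadjusted p-values below 0.05 with the trend and 1361 and 1216 without. The number of fragments is unknown, so the counting error of low values is not given.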

Other observations

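The shares of transcripts 2-fold different between libraries of a stage were set out by class of change between the stages, and the differences between classes were not tested. The classes were taken from the parental group left out of each comparison, so their members differ between comparisons. For 0.156 µM against control at 24 hpf, 6.01% of the transcripts at least 4-fold lower at 96 hpf were 2-fold higher than control and 5.12% 2-fold lower. The shares were 2.52% and 2.41% of those at least 4-fold higher at 96 hpf, and 2.31% and 1.85% of those that changed less than 2-fold between the stages. At 96 hpf the shares of these 3 classes, in the same order, were 5.30% and 5.12%, 1.41% and 2.35%, and 1.90% and 2.07%. For 0.078 µM against control they were 5.52% and 6.40%, 1.70% and 1.49%, and 1.64% and 1.87% at 24 hpf, and 7.27% and 6.10%, 1.28% and 1.86%, and 1.53% and 1.80% at 96 hpf. Between the doses, with the classes taken from control, they were 7.39% and 4.37%, 2.08% and 2.19%, and 2.42% and 1.81% at 24 hpf. At 96 hpf they were 5.38% and 6.22%, 2.25% and 1.81%, and 1.97% and 1.69%.

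Each parental group had transcripts with a level of its own at both stages, counted under limits chosen after the data were seen. Control was below 1 FPKM at both stages, with the other 4 libraries above 1 FPKM and at least 4-fold higher, for 10 transcripts, against 8 for 0.078 µM and 9 for 0.156 µM in its place. The reverse held for 13 transcripts of control, 9 of 0.078 µM and 16 of 0.156 µM. With limits of less than 0.1 FPKM at both stages and at least 5 FPKM in the other 4 libraries, the first condition held for 1 transcript of control, ENSDART00000005191, and for 0 of either copper group. The reverse under these limits held for 0 of control, 3 of 0.078 µM and 1 of 0.156 µM.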
